A study of Homo sapiens with 6 samples.

How the data were processed

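The data are 6 single-colour expression arrays of HCT116, a colorectal cancer line with microsatellite instability, carrying a doxycycline-inducible gene. The sample titles name wild-type ACVR2 as that gene, while the source labels list TGFBR2, ACVR2 and AIM2 together; the samples were taken as ACVR2 cells from the titles. All 6 samples received activin A, the ligand of the receptor that ACVR2 encodes; 3 were given doxycycline and 3 were not. The array is a focused glycogene chip. Total RNA was extracted with Trizol and turned into biotin-labelled cRNA by the Affymetrix procedure, per the labels' protocols. The labels give no time of induction, no dose and no statement that the replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

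The deposited table holds log2 expression values for 1259 probe sets on each of the 6 arrays. The authors made these values with RMA, per the submitters' processing notes, which name no version; RMA corrects the background, quantile normalizes the arrays and summarises the probes of each probe set. Whether further steps followed is not given in the sources used here. The table holds no detection calls, so how many probe sets lie near the background is unknown. Array medians lay between 7.61 and 7.65 log2 units, and lower quartiles between 6.85 and 6.89. Among the genes named below, B3GALT2, ST8SIA1, CLEC4A, SRGN, GPC6, SIGLEC9, SIGLEC11, VCAM1, IL17A and LUM had both group means under 6.85. Their differences come from dim probe sets, where the share of background is unknown. Scanner files were not used here.

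Probe sets were named through the RefSeq accession inside their identifiers, without its version, and a table of RefSeq genes for the GRCh38.p14 assembly. Of the 1259 probe sets, 1043 (82.8%) had 1 symbol, 190 carried no RefSeq accession and 26 carried an accession outside the table. No probe set had several symbols and none was a control. The named probe sets covered 927 genes, 93 of them with more than 1 probe set. All 1259 were tested, and unnamed ones are not named in the text. No coordinates were used, because the array table names no genome build. Gene spans from the same assembly, introns included, served only to look for a technical trend, for the 82.8% of probe sets that had one.

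Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, a group-means model, two-sided moderated test). P-values were adjusted by the Benjamini-Hochberg method over 1259 probe sets, at a threshold of 0.05. Neither a replicate block nor a filter on dim probe sets entered the fit. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays. Differences are given as log2 values with doxycycline minus those without. For single genes an exact two-sided permutation test of 3 arrays against 3 was added; the smallest p it can give is 0.1. The number of arrays limits the precision: the median 95% confidence interval of a difference reached 0.152 log2 units to either side.

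Before the data were examined, 27 gene lists were fixed, covering glycan synthesis and degradation, lectins, proteoglycans, activin and TGF-beta signalling, and markers of other cells. Each list with at least 5 measured genes was tested with camera (preset correlation 0.01, two-sided) over the 927 genes, with adjustment over the 26 lists that qualified. An estimated correlation and fry were run as alternatives. Members were also counted past the threshold over all probe sets and adjusted over the list alone.

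The genes named were also set by a rule fixed before the data were examined. It takes the study genes ACVR2A, TGFBR2 and AIM2, every receptor or SMAD list member that passes, and up to 15 genes with the largest rise and 15 with the largest fall among those that pass with fully separated arrays. Where fewer than 5 pass in a direction, it takes those with the smallest raw p up to 5, as not past the threshold. In each list it takes up to 4 members with the smallest raw p. No probe set was named AIM2 through the table, so that gene is not analysed here. A further gene that the rule takes is not reported here. Other genes appear only where the text says that they were chosen after their values were seen.

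The fit was tested on simulated data for the comparison of 3 against 3 arrays and 1259 probe sets, of which 200 were changed. With the real fit's own residuals kept on their arrays, it recovered 73% of changes of 0.5 log2 and 92% of changes of 1 log2. These residuals average 0 within each group, so unchanged probe sets had no difference, and the 0 false calls among 165 were fixed in advance. The planted differences also carried no error there, so that recovery shows only how the spread limits the calls. With Gaussian noise the fit recovered 81% and 96%, with 9 false calls among 186. That noise was independent between probe sets and equally wide in both groups, unlike the real arrays. In both versions the 200 planted changes also loosen the adjusted threshold, so the recovery may overstate what the real comparison could find.

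Alternatives fixed beforehand were the replicate number as a block, a further quantile normalization, median centring, keeping only the brighter 944 or 630 probe sets, trended and robust moderation, array weights, other thresholds, averaged probe sets, and leaving out each array in turn. Added after seeing the data were a correction for a trend with gene span, named probe sets only, a component of the within-group spread as a covariate, and other tests of the lists without 1 array. Figures were drawn with matplotlib 3.10.9.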

Results

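Expression of glycosylation genes was measured in HCT116 colorectal cancer cells in which, by the sample titles, the wild-type activin receptor gene ACVR2 could be switched on with doxycycline. The source labels list TGFBR2, ACVR2 and AIM2 together as inducible genes, so which of them these cells carried rests on the titles. Microsatellite-unstable tumours often lose this receptor. The comparison is meant to ask which glycan-related genes differ when it is re-expressed in the presence of activin A. No sample received doxycycline without the inducible gene, so an effect of the drug itself cannot be told apart from one of the receptor. No sample lacked activin A, so its part cannot be told either. There were 3 arrays from cells given doxycycline and 3 from cells without it, each with values for 1259 probe sets on the log2 scale.

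The probe set for ACVR2A, the gene that doxycycline was meant to induce, was not higher on the arrays labelled with doxycycline. Its level was 8.08 ± 0.07 (SD, n = 3) with doxycycline and 8.34 ± 0.32 (SD, n = 3) without. The difference was -0.26 log2 units (SE 0.16; limma, adjusted p = 0.710), and the exact permutation p was 0.3. The arrays with doxycycline read 8.15, 8.02 and 8.08 for replicates 1, 2 and 3, and those without read 8.25, 8.07 and 8.70. Leaving out replicate 3 without doxycycline moved the difference to -0.08, so that array sets most of it. With the first component of the within-group spread as a covariate, a setting chosen after seeing the data, the difference of -0.26 passed as a lower value (limma, adjusted p = 0.0262). That component is taken from the residuals of the same arrays, so this p is too small and is no evidence of a lower value. Whether the probes lie within the introduced sequence is not known, and a probe set outside it would not register the transgene. The measurement therefore does not settle the labels, and the arrays are named by label throughout.

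Most receptors of the pathway had lower values on the arrays labelled with doxycycline, none past the threshold. TGFBR2, the type II receptor for TGF-beta, differed by -0.35 (SE 0.21; limma, adjusted p = 0.704), and ACVR2B, a second activin receptor, by -0.52 (SE 0.23; limma, adjusted p = 0.673). ACVRL1, a type I receptor, was at -0.05. Of the list of receptors and SMADs 12 members were measured, all of them receptors; 10 had lower values and 2 higher, with 0 past the threshold and a median of -0.09. The list did not pass (camera, adjusted p = 0.571; adjusted p = 0.950 with an estimated correlation). Replicate 2 without doxycycline had the lowest value of its group for TGFBR2 (9.21) and ACVR2B (8.80), so leaving it out enlarges both differences. Without replicate 3 of the cells not given doxycycline the median was -0.02, and the differences of TGFBR2, ACVR2B and ACVRL1 were -0.16, -0.31 and -0.09.

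That array stood apart from the other 5. Its correlations with them across probe sets ran from 0.982 to 0.991, while those among the other 5 ran from 0.995 to 0.999. It scored 10.1 on a first principal component that held 73.1% of the variance. Replicate 1 without doxycycline came next at 1.51, and the rest lay between -3.15 and -2.54. Replicate 1 also had the largest mean squared deviation of the others (0.0294), and its deviations correlated with those of replicate 3 (Spearman 0.610, probe sets not being independent). Leaving out replicate 3 therefore does not remove what these 2 arrays share. The median SD of a probe set was 0.0902 among the arrays without doxycycline, 0.0457 among those with it, and 0.0541 for replicates 1 and 2 without doxycycline alone. The last value comes from 2 arrays, and a median SD of 2 values runs lower than one of 3. It is therefore not on equal footing with the others and does not show that replicate 3 alone widened the spread. No pair of arrays held identical values. Leaving this array out shrank the difference by over 1.5 times, or turned it, for 35 of the 102 named genes and enlarged it by over 1.5 times for 2.

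**Figure D1:**
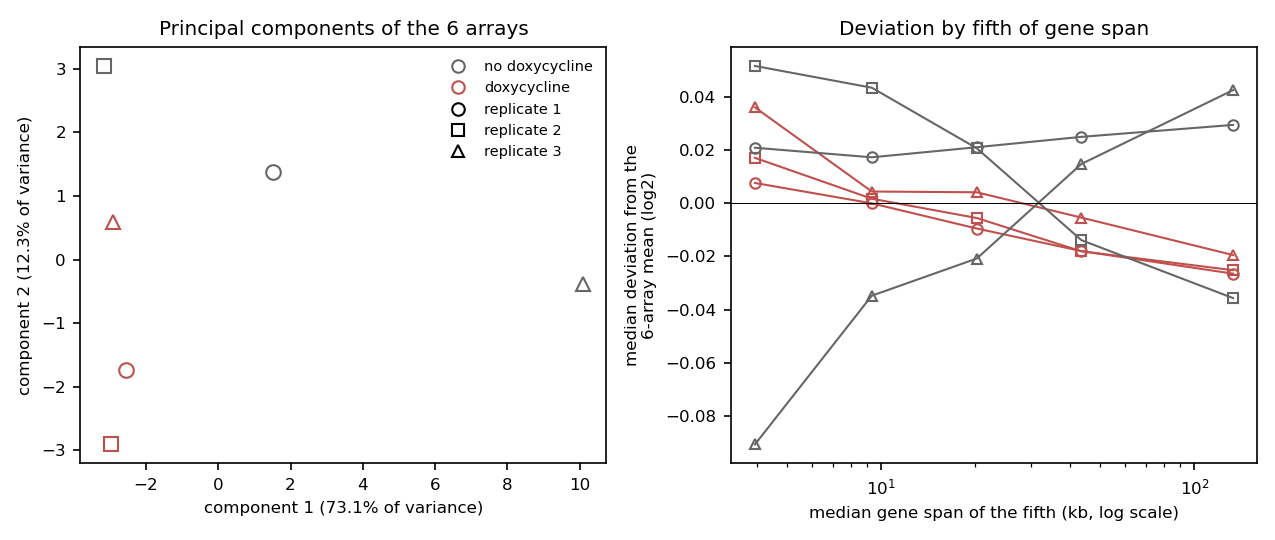
Left, scores of the 6 arrays on the first 2 principal components (grey, without doxycycline; red, with doxycycline; the symbol gives the replicate), which hold 73.1% and 12.3% of the variance; replicate 3 without doxycycline lies at 10.1 on the first. Right, median deviation of each array from the mean of all 6 (log2) for probe sets grouped into 5 equal bins of gene span (kb, log scale), in the same colours and symbols, where that array has the lowest median among the shortest genes and the highest among the longest.

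Among single genes, the sulphotransferase gene GAL3ST4 gave the smallest p of the genes with lower values in the arrays labelled with doxycycline. Its level was 7.98 ± 0.05 with and 8.41 ± 0.07 without (SD, n = 3 each), 1.34-fold higher without doxycycline, and its other probe set differed by -0.50. MST1R, a receptor tyrosine kinase also called RON, differed by -0.32 (SE 0.05), IGF2R, the receptor that carries mannose 6-phosphate-bearing enzymes to lysosomes, by -0.33 (SE 0.07), NOTCH1 by -0.30 (SE 0.06), and CHST3, a chondroitin 6-sulphotransferase, by -0.24 (SE 0.05). With higher values were FGF18, a fibroblast growth factor, at 0.28 (SE 0.05), the BMP antagonist gene NOG at 0.27 (SE 0.06), the transporter-family gene SLC35E3 at 0.24 (SE 0.05), the lysosomal amidase gene NAAA at 0.21 (SE 0.05) and the lysosomal sialidase gene NEU1 at 0.31 (SE 0.08). A further NEU1 probe set was at 0.40, whereas the other NAAA probe sets were at 0.0037 and -0.03. For each of these 10 genes all 3 arrays of one group lay beyond all 3 of the other.

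None of these passed. With limma, 0 of 1259 probe sets were past an adjusted p of 0.05, the smallest being 0.158. At an unadjusted p under 0.05 there were 98 probe sets, 41 higher and 57 lower with doxycycline, where 62.95 would be expected by chance. This split turned when each array was centred on its median (63 higher, 44 lower) and when the arrays were quantile normalized again (61 higher, 51 lower), without replicate 1 of the cells not given doxycycline (52 higher, 42 lower) and with a trend against gene span removed (54 higher, 48 lower). With array weights it was 74 higher and 172 lower. The groups were fully separated for 15.8% of probe sets, against 10% by chance, with 95 above and 104 below. Differences lay within 0.1 log2 units for 64.2% of probe sets and within 0.5 for 97.5%. With array weights, which gave the array standing apart a weight of 0.198, 1 probe set passed, the GAL3ST4 one at -0.49 (limma, adjusted p = 0.0378). With the covariate for within-group spread 133 passed, 60 of them higher, among them 37 of the 102 named genes. Its p-values are too small, because the covariate is taken from the residuals of the same fit.

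**Figure D2:**
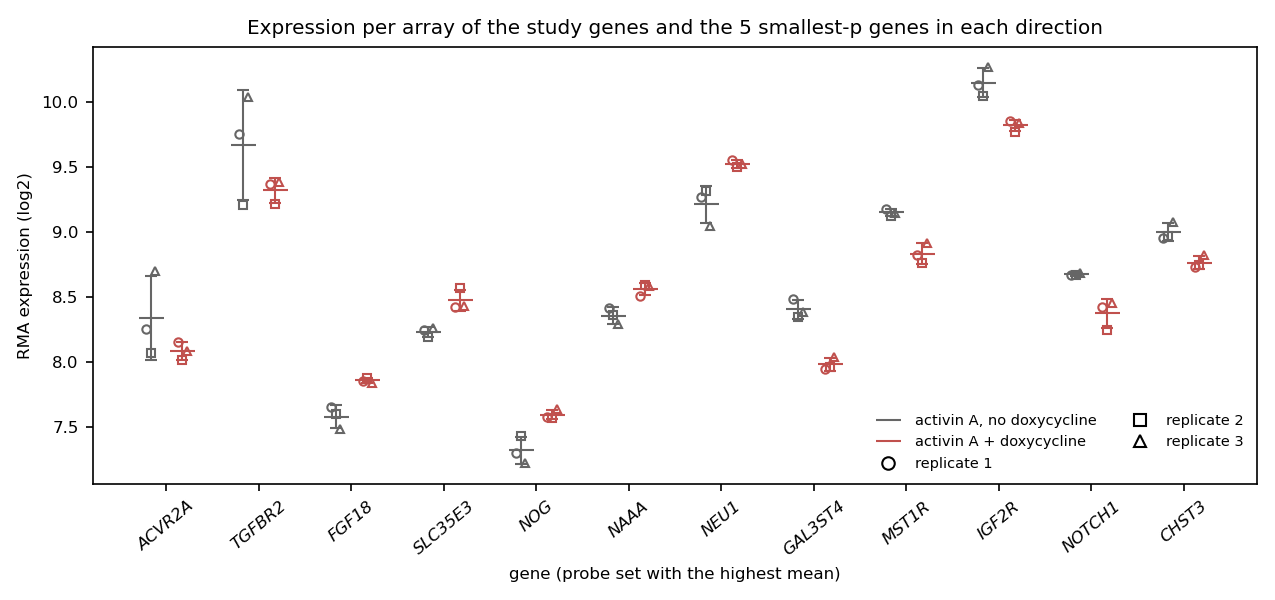
RMA expression (log2) on each array for ACVR2A, TGFBR2 and the 5 genes with the smallest p in each direction, without (grey) and with (red) doxycycline; symbols mark replicates, horizontal bars the mean and whiskers the SD (n = 3). ACVR2A and TGFBR2 overlap between the groups, while the other 10 genes are separated and have adjusted p-values of at least 0.158.

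Genes that build and transfer the N-glycan precursor had mostly higher values in the arrays labelled with doxycycline. Of 20 measured, 13 were higher and 7 lower, with a median of 0.09 and 0 past the threshold. ALG11, a mannosyltransferase, was at 0.60 (SE 0.25), ALG13, part of the enzyme that adds the second GlcNAc, at 0.24 (SE 0.09), and ALG8, a glucosyltransferase, at 0.18 (SE 0.08). For ALG11 the groups overlapped: replicates 1, 2 and 3 read 7.81, 8.22 and 7.21 with doxycycline, and 7.13, 7.07 and 7.26 without. DPAGT1, which begins the precursor, was at -0.12 (SE 0.05). The list did not pass (camera, adjusted p = 0.168; adjusted p = 0.912 with an estimated correlation). Without replicate 3 of the cells not given doxycycline its median was 0.07, ALG13 was at 0.15, ALG8 at 0.10, and camera gave an adjusted p of 0.000927, with an adjusted p of 0.93 once the correlation was estimated. Genes of N-glycan trimming and branching had lower values in 11 of 14 cases, with a median of -0.08 that was -0.03 without that array. The mannosidase genes MAN1A1 and MAN2A2 were at -0.40 and -0.22, and the branching enzyme genes MGAT5 and MGAT5B at -0.08 and 0.15 (camera, adjusted p = 0.571). Without that array MAN1A1 was at -0.18, MAN2A2 at -0.13 and MGAT5B at 0.07. Of genes for glycoprotein folding in the endoplasmic reticulum only CANX and UGGT2 were measured, too few for a test. They were at -0.22 and -0.28, and at -0.01 and -0.08 without that array. Replicate 2 without doxycycline had the lowest values of its group (9.45 and 8.33), so leaving it out instead enlarges both differences.

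Genes for O-mannose, O-GlcNAc and other O-linked sugars had lower values in 8 of 10 cases, with a median of -0.13. OGT, the enzyme that adds O-GlcNAc to nuclear and cytoplasmic proteins, had the largest negative difference of all probe sets at -1.03 (SE 0.32; limma, adjusted p = 0.478), and was at -0.71 without replicate 3 of the cells lacking doxycycline. POMT1 and POMT2, which together begin O-mannose chains, were both at -0.23 (SE 0.07 and 0.08), and the fringe gene MFNG at -0.12. The list did not pass (camera, adjusted p = 0.246; adjusted p = 0.912 with an estimated correlation). In the Notch pathway, whose receptors carry such sugars, 8 of 20 genes were higher and 12 lower. The ligand genes JAG2 and JAG1 were at -0.57 (SE 0.14) and -0.51 (SE 0.24), the latter at -0.31 without that array. PSENEN, a subunit of gamma-secretase, had the largest positive difference of all at 0.94 (SE 0.27; limma, adjusted p = 0.477), and 0.64 without the array standing apart. The median of the Notch list was -0.05 and its mean 0.0091 (camera, adjusted p = 0.857).

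Mucin-type O-glycan genes had a median of -0.03, with 8 of 23 higher and 15 lower. C1GALT1C1, the chaperone of the core 1 galactosyltransferase, was at 0.25 (SE 0.07), the initiating GalNAc-transferase genes GALNT6, GALNT13 and GALNT18 at 0.17, -0.14 and -0.28. Sialyltransferases had 9 of 20 higher and 11 lower, with a median of -0.01 and a mean of 0.0058. ST6GALNAC2 and ST6GALNAC5 were at 0.28 (SE 0.08) and 0.17 (SE 0.05), and ST3GAL1 and ST6GAL1 at -0.19 (SE 0.06) and -0.31 (SE 0.17). Among fucosyltransferases and the genes of GDP-fucose supply, 7 of 17 were higher and 10 lower, with a median of -0.01. POFUT4, formerly FUT11, was at 0.24 (SE 0.06), POFUT2 at 0.08, FUT3 at -0.08 and FUT4 at -0.27. Chain elongation genes had 11 of 24 higher and 13 lower, with B4GALNT4 at -0.45, GCNT2 at -0.14, B3GALT2 at -0.10 and B4GAT1 at 0.20. Genes of glycosphingolipid synthesis had 8 of 18 higher and 10 lower, with ST3GAL2 at 0.13, ST8SIA1 at -0.06 and B4GALT6 at -0.31. Several of these values were smaller without replicate 3 of the cells not given doxycycline: B4GALT6 was then at -0.01, ST3GAL2 at 0.04, ST6GAL1 at -0.17, FUT4 at -0.15, POFUT2 at 0.05, GALNT6 at 0.09 and B4GAT1 at 0.11. Camera gave adjusted p-values of 0.857 for the mucin-type and sialyltransferase lists, 0.986 for fucosylation and for chain elongation, and 0.911 for glycosphingolipids.

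The list of carbohydrate sulphotransferases was the only one with members past the threshold when adjusted over the list alone. These were 2 of its 25 measured genes, GAL3ST4 (limma, adjusted p = 0.00627) and CHST3 (limma, adjusted p = 0.0487), both with lower values on the arrays labelled with doxycycline. Over all probe sets 0 members of this list passed. CHST3 is also in the list of heparan and chondroitin sulphate synthesis, where it did not pass over that list alone (limma, adjusted p = 0.179). Adjustment over a list alone does not allow for the 27 lists examined. CHST11, a chondroitin 4-sulphotransferase, was at 0.32 (SE 0.09) and the tyrosine sulphotransferase gene TPST1 at 0.24 (SE 0.08), and the list had 16 higher and 9 lower genes (camera, adjusted p = 0.857). In heparan and chondroitin sulphate synthesis 19 of 46 genes were higher and 27 lower, with a median of -0.02. NDST1, which begins the sulphation of heparan sulphate, was at -0.23 (SE 0.07) and EXTL3, which acts at the start of its chains, at -0.19 (SE 0.07). Proteoglycan core proteins had 12 of 31 higher and 19 lower, with SPOCK2 at -0.14, AGRN at -0.29, SRGN at 0.11 and GPC6 at 0.09. Camera gave adjusted p-values of 0.719 for chain synthesis and 0.857 for core proteins.

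Nucleotide sugar synthesis had 17 of 25 genes higher and 8 lower, and nucleotide sugar transport 11 of 15 higher and 4 lower. NAGK, the N-acetylglucosamine kinase, was at 0.57 (SE 0.18), the sialic acid synthase gene NANS at 0.45 (SE 0.17), hexokinase HK1 at -0.30 (SE 0.07) and GPI at -0.27 (SE 0.13). Without the array standing apart NAGK was at 0.37, NANS at 0.25 and GPI at -0.14. SLC35B1, SLC35D1, SLC35E1 and SLC35B4 were at 0.31, 0.10, 0.44 and -0.34, and at 0.14, 0.05, 0.15 and -0.16 without it. The medians were 0.07 for synthesis and 0.06 for transport, and 0.02 and 0.01 without that array (camera, adjusted p = 0.571 for both with all arrays). Genes that break down glycans had 15 of 33 higher and 18 lower, with a median of -0.03 (camera, adjusted p = 0.857). The iduronate sulphatase gene IDS was at 0.41 (SE 0.12), CTBS at 0.15 (SE 0.05) and the heparanase gene HPSE at 0.15 (SE 0.06), beside NEU1. Further probe sets of IDS and CTBS were at 0.19 and 0.08, with overlapping groups.

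**Figure D3:**
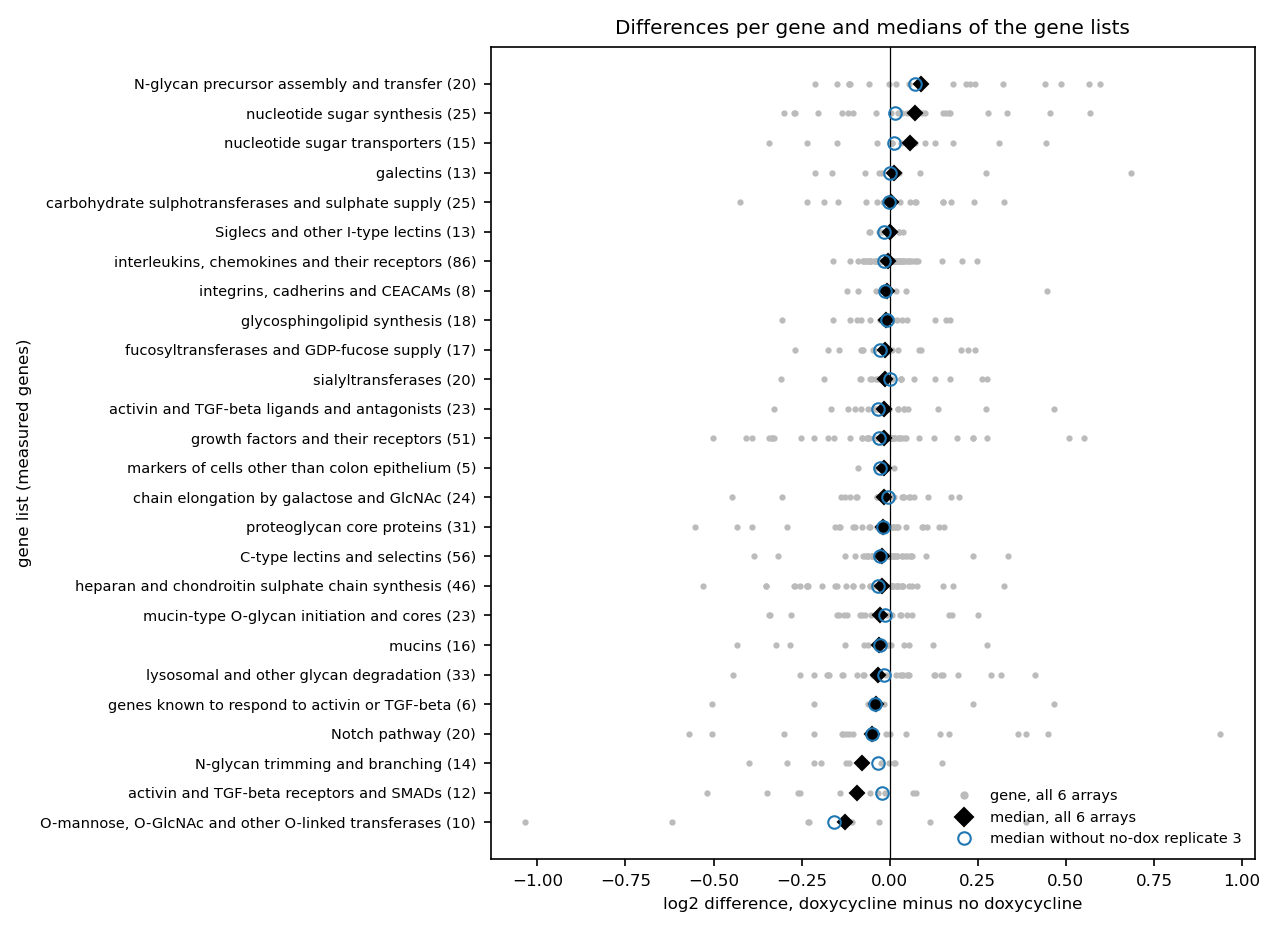
Log2 difference, doxycycline minus no doxycycline, of each measured gene (grey dots) in the 26 gene lists with at least 5 measured genes, with the list median over all 6 arrays (black diamonds) and without replicate 3 of the cells not given doxycycline (open circles). Medians ran from -0.13 for O-mannose and O-GlcNAc genes to 0.09 for the N-glycan precursor list, and 0 of 26 lists passed with all arrays.

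Of galectins, 8 of 13 were higher and 5 lower. LGALS3 was at 0.68 (SE 0.27) and 0.36 without the array standing apart, LGALS1 at 0.27 and 0.06 without it, LGALS3BP at -0.21 and LGALS12 at -0.07. C-type lectins and selectins had 18 of 56 higher and 38 lower, with KLRK1 at -0.32 (SE 0.10), CLEC4A at -0.13 and ATRN at -0.39. Siglecs had 7 of 13 higher and 6 lower, and SIGLEC8, SIGLEC9, SIGLEC10 and SIGLEC11 lay between -0.06 and 0.04. Mucins had 5 of 16 higher and 11 lower, with OVGP1 at -0.32 (SE 0.10), PODXL at -0.43, MUC1 at -0.13 and EMCN at 0.28 (SE 0.10). Integrins, cadherins and CEACAMs had 3 of 8 higher and 5 lower, with ICAM3 at 0.45, MCAM at -0.12, PECAM1 at -0.09 and VCAM1 at 0.05. Without the array standing apart LGALS3BP was at -0.11, ATRN at -0.20, PODXL at -0.26, EMCN at 0.18 and ICAM3 at 0.24. Camera gave adjusted p-values of 0.857 for galectins and for mucins, 0.571 for C-type lectins, and 0.986 for Siglecs and for integrins.

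Among activin and TGF-beta ligands and antagonists, 8 of 23 were higher and 15 lower. Beside NOG, the ligand gene BMP4 was at -0.33 (SE 0.10), BMP8B at -0.17 (SE 0.05) and TGFB1 at 0.47 (SE 0.27). TGFB1 varied widely without doxycycline, at 8.29, 9.34 and 8.66 for replicates 1, 2 and 3, and its groups overlapped. Of genes known to respond to these ligands only 6 were measured, 2 higher and 4 lower, with VEGFA at -0.22 (SE 0.08) and PDGFB at 0.24 (SE 0.09). Growth factors and receptors had 21 of 51 higher and 30 lower, and the neuregulin gene NRG1 was at 0.51 (SE 0.13), while its other probe sets were at 0.0087 and 0.0093. Interleukins, chemokines and their receptors had 37 of 86 higher and 49 lower, with CXCL2 at -0.16, IFNGR2 at 0.25, IFNAR2 at 0.20 and IL17A at 0.08. IFNGR2 was at 0.13 and IFNAR2 at 0.12 without the array standing apart. Markers of cells other than colon epithelium, of which 5 were measured, had a median of -0.02, with PECAM1 at -0.09, NCAM1 at -0.04, PDGFRB at -0.02 and LUM at 0.01. Camera gave an adjusted p of 0.857 for each of these 5 lists.

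Across the 27 lists, 0 members passed over all probe sets, and 0 of the 26 lists tested passed with camera, with an estimated correlation or with fry. Camera ranks a list against the other genes, so its direction can differ from the sign of a median near 0. For the glycan degradation, sialyltransferase, glycosphingolipid, chain elongation, integrin and interleukin lists it pointed up while the median was below 0, and for Siglecs it pointed down with a median of 0.0012. Without replicate 3 of the cells not given doxycycline 3 medians near 0 turned, to 0.0006 for sialyltransferases, -0.0027 for sulphotransferases and -0.015 for Siglecs. Others moved by over 1.5 times, to -0.015 for glycan degradation and for interleukins, -0.033 for heparan and chondroitin sulphate synthesis, -0.013 for mucin-type O-glycans, -0.029 for fucosylation and for markers of other cells, -0.0060 for chain elongation, 0.0011 for galectins, -0.030 for growth factors, -0.032 for activin and TGF-beta ligands and -0.014 for integrins.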

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

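The alternatives that correct for gene span, add a covariate, keep named probe sets only or combine the omission of an array with another list test were chosen after seeing the data. Among the settings run, the count of 0 probe sets changed under 2. Array weights gave 1 (limma, adjusted p = 0.0378, GAL3ST4), and the cause was not tested. The first component of the within-group spread as a covariate gave 133, but it is taken from the residuals of the same fit, so its p-values are too small. The count was 0 under the other settings, among them a fold of at least 1.5, an adjusted p under 0.01 and averaged probe sets. The count of lists was 0 except without replicate 3 of the cells not given doxycycline, where it was 1, and leaving out each array in turn gave 0 to 1. Without that array it was 0 again with an estimated correlation (smallest adjusted p = 0.93) and with fry (0.188). ACVR2A stayed at a value below 0, from -0.39 to -0.08 when single arrays were left out, and was past the threshold at -0.2561 with the covariate alone (adjusted p = 0.0262). When single arrays were left out, unadjusted counts ran from 45 (without replicate 1 with doxycycline) to 258 (without replicate 2 without doxycycline), with 53 without replicate 2 with doxycycline. They were 246 under array weights, 335 with the covariate and 63 among the brighter 630 probe sets, where fewer were tested. The replicate numbers showed no sign of pairing the arrays: deviations of equal numbers correlated at -0.147, -0.0428 and -0.157. Deviations sum to 0 within each group, so a higher correlation with another number, up to 0.212, then follows and adds nothing. With 3 arrays per group a shared culture or day cannot be excluded. With the replicate number as a block, 0 probe sets and 0 lists passed, 81 probe sets were at an unadjusted p under 0.05 and ACVR2A was at -0.26. All probe sets whatever their species equals the reported setting, as the table names no species and holds no control probe sets. The table gives no background, so the limit that dim signal sets cannot be stated.

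Of 1485 values of the 102 named genes under alternatives, 1438 kept their direction and their side of the threshold. With the covariate 37 passed, 18 higher and 19 lower, and under the other alternatives 1. The 4 genes that turned lay near 0. LUM was at -0.0049 quantile normalized again, -0.0080 with the span trend removed and -0.0025 to 0.036 when single arrays were left out. PDGFRB was at 0.0040 centred, 0.031 with the span trend removed and -0.030 to 0.012 when single arrays were left out. NCAM1 was at 0.00086 with array weights and 0.018 with the span trend removed, where ST8SIA1 was at 0.022.

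Of 385 list values, 40 in 13 lists turned the direction that camera gives, each at an adjusted p of at least 0.379, and 1 passed. The medians there were, for Siglecs, 0.0012 with the block, with trended moderation and with the covariate, 0.011 quantile normalized again, 0.021 centred and -0.00031 with array weights. Fucosylation had -0.014 quantile normalized again, -0.011 among the brighter 944 probe sets and 0.0057 among the brighter 630. In these sets integrins had -0.012 (944), chain elongation -0.032 (630) and glycosphingolipids -0.080 (630). Chain elongation had -0.016 with trended moderation and with the covariate, where glycosphingolipids had -0.0098 and Notch -0.051; Notch had -0.018 with array weights. With the span trend removed, medians were 0.0040 for mucin-type O-glycans, -0.013 for galectins, -0.033 for interleukins, 0.0034 for growth factors and 0.018 for markers of other cells. Leaving out single arrays gave -0.021 to 0.016 for Siglecs, -0.029 to 0.0013 for fucosylation, -0.0135 to 0.0179 for chain elongation and -0.031 to -0.0081 for glycosphingolipids. It gave -0.026 to 0.0017 for integrins, -0.091 to -0.00091 for Notch, -0.062 to -0.013 for mucin-type O-glycans and -0.015 to 0.0044 for interleukins. It gave -0.030 to -0.0047 for growth factors, -0.032 to -0.0071 for activin and TGF-beta ligands, and -0.058 to -0.018 for genes responding to them. The cause of these turns was not tested.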

Other observations

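The tests of gene span on replicate 3 without doxycycline, the splits of the arrays for probe sets, the covariate and the further list tests without that array were chosen only after the result was seen.

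MST1, the gene for the ligand of the MST1R receptor, had lower values on the arrays labelled with doxycycline, as did its receptor; the gene was chosen after its values were seen. Its probe sets differed by -0.44 (SE 0.06; limma, adjusted p = 0.213) and -0.25 (SE 0.08; limma, adjusted p = 0.477), in both cases with all 3 arrays below the other 3. MST1 has near-identical copies in the genome, and whether the probes tell them apart is not known.

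Replicate 3 without doxycycline differed from the other 5 arrays in named genes, chosen after their values were seen. VCAN, a large proteoglycan core protein, was 1.49 log2 units above their mean, OGT 1.39 and OGA, which removes the sugar OGT adds, 1.06. At the other end PSENEN was at -1.28, DPM3, a subunit of dolichol-phosphate-mannose synthase, at -1.27, LGALS3 at -1.18 and DAD1, a subunit of oligosaccharyltransferase, at -1.13. In all, 82 of 927 genes were over 0.5 log2 units higher and 81 lower, where the most in any of the other arrays was 18. Against the mean of all 6 arrays, the 40 ribosomal protein genes had a median deviation of -0.265 on this array, where all genes had -0.0128.

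The mean squared deviation of that array was 4.005 times the largest of the others, and 3.915 times over the 1043 probe sets with a gene span. With a trend against span removed from these the ratio was 3.69, and over all probe sets with the arrays quantile normalized again 4.13, which argues against the span trend as the whole cause and against a difference in distribution that another quantile normalization would remove. The deviation correlated with span across probe sets (Spearman 0.394, genes not being independent), and 15.5% of its squared size lay along the span trend. The largest size in the other arrays was lower, at 0.285, against a mean without this array. Against the mean of all 6, which includes this array's own trend, replicate 2 without doxycycline had -0.397. The group difference correlated with span at -0.246 with all arrays and at 0.00192 without this one. A trend with span is therefore present on this array. Replicates 1 and 2 without doxycycline also differed along span (0.313), so whether span has a part in the cause stays open. RNA quality and a difference between cultures were not tested, and no biological explanation was tested.

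The N-glycan precursor list had higher values with doxycycline once that array was left out, which is a hypothesis from 5 arrays. Of 20 genes 15 were higher, with a median of 0.07 against -0.02 over all genes, and 0 members passed; ALG14, chosen after its values were seen, was at 0.18 and ALG13 at 0.15. The median lay at percentile 99.96 of 10000 lists matched on mean expression, and camera gave an adjusted p of 0.00519 with the span trend removed, which argues against a trend with expression level or with span as the cause. Of the 10 splits of the 5 arrays, 1 gave a camera p as small, the real one at 3.57e-05 with the lowest other at 5.86e-05, and 10 splits are too few for a share under 0.05. With an estimated correlation, which was 0.042, the adjusted p was 0.93, and with fry 0.188, so the list passed with neither. The rise to 0.93 is no sign by itself of a shared deviation of these genes. With all arrays the O-mannose and O-GlcNAc list had an estimated correlation of -0.056, below the preset 0.01. Its unadjusted camera p still rose from 0.019 to 0.070, while that of sialyltransferases (-0.032) fell from 0.5795 to 0.5786. A shared deviation between single arrays may still account for the N-glycan precursor list, as may induction of the receptor, which was not shown on these arrays.

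With the first component of the within-group spread as a covariate, 133 probe sets passed, 60 of them higher, among them OGT at -1.03, PSENEN at 0.94, ACVR2A at -0.26 (limma, adjusted p = 0.0262) and ACVR2B at -0.52 (limma, adjusted p = 0.0254). That component is built without the group difference, so it can lower the spread but not move the differences, and it takes up 1 direction chosen to be the widest. Of the 10 splits of the 6 arrays 2 gave as many. The highest other gave 140, with replicates 1 and 3 without doxycycline set beside replicate 3 with it. Further splits that mix the groups gave 95, 49 and 43, and the rest 0. A count as large therefore does not need the real grouping, and 10 splits are too few for a share under 0.05. The component is taken from the residuals of the same fit, so p-values with it are too small, and the 133 calls are no evidence of a difference. Without the covariate the real counts were 0 probe sets and 0 lists, which all 10 splits reach by construction, so these counts say nothing about chance; the highest other split gave 0 probe sets and 1 list. At an unadjusted p under 0.05 the real split gave 98 probe sets and the others from 9 to 88, and 10 splits are too few to judge this difference.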
